A study of Mus musculus with 2 samples.

How the data were processed

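p53-bound DNA and input DNA were sequenced from mouse embryonic stem cells treated with Nutlin, with 1 library each. Samples were assigned to the p53 ChIP or the input group by their titles. ChIP-seq libraries were made with an NEB ChIP-seq kit after phenol extraction, per the labels' protocols.

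The deposited file is a list of 92924 peaks without a header, each with a chromosome, start, end, name and score. The submitters' processing notes name CASAVA 1.8.2, MACS 1.4.1 and the genome build mm9. The aligner, the read totals, the treatment of duplicate reads and the settings of the peak caller are not given in the sources used here, so depth per sample is unknown. The score values were deposited as the authors' peak caller wrote them; the lowest is 50, and MACS 1.4 writes −10 × log10 of the p-value against input, on which 50 is p = 1e-05. A score of this kind grows with read depth as well as with enrichment, so peaks were compared only inside this list. The peak names run from 1 to 92924 without a break. Start positions were deposited by the authors in the BED convention, counted from 0, and are printed here counted from 1. The list was called from a single ChIP library against a single input library, so p-values over peaks or bins describe positions inside this list and do not measure the spread between cultures or conditions.

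No genome sequence was used here, and the gene table at hand is on GRCm38. Since the submitters' processing notes give mm9, no gene positions were used. Of 11 results planned before the data were examined, 8 need the mm9 sequence or gene annotation and were not run: the share of peaks at promoters, its value for strong peaks, the p53 motif and its trend with score, other motifs, base composition, and the occupancy of 13 fixed gene lists and of olfactory receptor genes. The rule for named items was the 10 highest-scoring peaks by position, ties broken by chromosome and start, in place of named genes. The plan foresaw counts per chromosome only where lengths are not given. Densities per Mb, added after seeing the file, used the distance from the first to the last peak of a chromosome as its length, which leaves out unassembled ends. No density is given for Y, whose 6 peaks span a small part of it.

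Peaks were analysed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and drawn with Matplotlib 3.10.9. Density ratios have exact conditional 95% intervals for 2 Poisson counts and a permutation p from 1000 random assignments of peaks to chromosomes in proportion to length. Shares of peaks have exact Clopper-Pearson 95% intervals, and medians have 95% bootstrap intervals (1000 resamples). These intervals treat peaks as independent, which neighbouring peaks are not. Spacing was compared with 1000 random placements of each peak, at its own width, between the first and last peaks of its chromosome; a peak was near the next if at most 10 kb separated them. Because such shares depend on the number of peaks, strong peaks were also compared with 1000 random draws of the same number of peaks from the list, a test added after seeing the data. Bins of 1 Mb were counted by peak midpoint and kept where they lay wholly between the first and last peaks. Functions for ratios, spacing and bin variation were tested on simulated lists: a planted autosome-to-X ratio of 6 was recovered as 5.81 in 69400 simulated peaks, uniform placement gave a spacing ratio of 1.00, and a planted excess variance of 0.5 was recovered as 0.512 in 68387 peaks.

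Alternatives planned for the results that could be run were a score minimum of 100, the 5000 highest-scoring peaks, merging of peaks up to 1 kb apart, and distances of 5 kb and 50 kb for spacing. Added after seeing the data were score minimums of 200, 500, 1000, 2000 and 3000, removal of peaks wider than 4 kb, random placement inside 1 Mb bins, density per occupied bin, merging for density and spacing, merging together with placement inside bins, and a ranking that places scores of exactly 3100 first.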

Results

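p53 is a transcription factor that binds DNA in a sequence-specific manner and is held at low levels by the ubiquitin ligase Mdm2. Nutlin is a small molecule that blocks the contact between Mdm2 and p53 and so lets p53 accumulate. The study asked where p53 sits on the genome of mouse embryonic stem cells, self-renewing cultured cells derived from the early embryo, after Nutlin. The cells were grown with leukemia inhibitory factor, which keeps them undifferentiated. They were exposed to Nutlin for 8 hours, fixed and processed for ChIP-seq, in which DNA bound by a protein is pulled down with an antibody and sequenced. The Nutlin dose was 20 in both places where it is given, but in µM in the series design and in mM in the sample protocols, so its unit is not settled here. The series holds 2 libraries, 1 from chromatin immunoprecipitated with a p53 antibody (M-19) and 1 from input chromatin, and both came from treated cells. The single comparison of the design is therefore p53 ChIP against input. Without an untreated library, no value below measures a response to Nutlin, and without replicates no value has an error between cultures.

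The p53 ChIP library was enriched over input at 92924 regions of the mouse genome (build mm9), all on the 19 autosomes, X and Y. The regions were narrow, with a median width of 509 bases (quartiles 417 and 639) and a range from 148 to 18655 bases. Together they covered 52.2 Mb, or 2.03% of the length between the first and last peaks of the chromosomes. Neighbouring peaks never overlapped, but 1991 of them lay within 100 bases of the preceding peak. The number of reads behind the peaks is unknown, because the list gives no read counts, and intervals below cover counting error of peaks only. The list also gives no false discovery rate and no fold over input, and no p53 motif was searched for. How many of the regions are sites of p53 binding is therefore open, and p53 peaks below means peaks of this list.

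Most p53 peaks were weak and a small class was very strong. Each peak carries the score the authors' peak caller gave it, which starts at 50 (p = 1e-05 on the −10 × log10 scale of this caller) and had a median of 87.5. Scores under 100 made up 57.0% of the list (53011 peaks), and scores of 1000 or more made up 5.77% (5361 peaks). A group of 1390 peaks had a score of exactly 3100, only 67 peaks lay between 3000 and 3100, and 116 peaks lay above 3100, up to 3233.06. Stronger peaks were wider. The median width was 448 bases (95% bootstrap interval 447 to 449) at scores of 50 to 100, 662 bases (657 to 666) at 200 to 500, and 829 bases (820 to 838) at 1000 or more. The rise was not steady at the top: the median was 771 bases (763 to 780) at 1000 to 2000 and 833 (817 to 859) at 2000 to 3000. It was 782 (742 to 895) in the 67 peaks at 3000 to 3100. Across all peaks, width and score had a Spearman rho of 0.61 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Peaks of a single list are not independent replicates. Width and score were also both set by the same peak caller, so their relation by itself is not evidence on p53 binding. Peaks at exactly 3100 were the widest class, with a median of 976 bases (953 to 1010), and peaks scored above 3100 had a median of 816 bases (779 to 906).

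**Figure D1:**
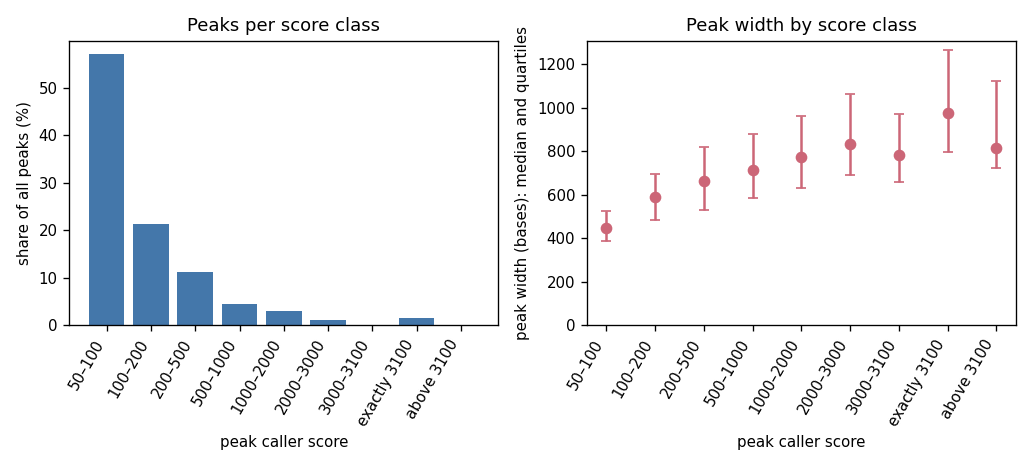
Left, share of the 92924 p53 peaks (%) in each class of peak caller score; right, peak width in bases per class, with points for medians and bars for the quartiles. Scores under 100 hold 57.0% of the peaks, and the widest class is the one at exactly 3100, with a median of 976 bases against 816 above 3100.

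The 10 highest scores in the list belonged to peaks on 10 different chromosomes, given here by mm9 position because no gene annotation of that build was used. The top score of 3233.06 was shared by peaks on chromosome 8 from 86577492 to 86578578, on chromosome 11 from 81025718 to 81026357 and on chromosome 19 from 41738465 to 41741039. The next was on chromosome 10 from 127046861 to 127047995 (score 3230.05), followed by chromosome 2 from 118463003 to 118463565 (3227.04) and chromosome 9 from 43879759 to 43880587 (3226.07). A score of 3225.28 was given to peaks on chromosome 6 from 4140819 to 4141481 and on chromosome 15 from 36300834 to 36301712. A score of 3224.03 closed the group, for peaks on chromosome 3 from 21737095 to 21738063 and on chromosome 5 from 75069522 to 75070516. A further peak with this score, on chromosome 9, fell outside the 10 by the rule for ties. Their widths ran from 563 bases on chromosome 2 to 2575 bases on chromosome 19. If the 1390 peaks at exactly 3100 are placed above all others and ranked by width, 0 of these 10 remain among the first 10. This follows by construction, since all 10 score above 3100. The order at the top of the list therefore depends on how the value 3100 is read. If 3100 stands for p-values too small to be stored, a reading taken up below, all 1390 rank above these 10 peaks.

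p53 peaks were spread unevenly over the chromosomes, and chromosome X held very few. The autosomes carried 38.6 ± 8.68 peaks per Mb (mean ± SD over 19 chromosomes), from 25.6 per Mb on chromosome 3 to 61.2 per Mb on chromosome 11. Chromosome 17 (48.4 per Mb), chromosome 5 (46.1 per Mb) and chromosome 19 (45.2 per Mb) followed chromosome 11. Chromosome 14 (27.1 per Mb) was nearest to chromosome 3 at the low end. The spread between autosomes was larger than in any of 1000 random assignments of the same peaks in proportion to length, in which autosomes ranged from 35.7 to 41.0 per Mb (one-sided permutation p = 0.000999, the smallest possible). Peaks of score 1000 or more varied in a similar range, from 1.62 per Mb on chromosome 3 to 3.41 per Mb on chromosome 11.

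Chromosome X carried 687 peaks, or 0.739% of the list, at 4.22 per Mb (95% Poisson interval 3.91 to 4.55). All autosomes pooled carried 38.2 per Mb, which was 9.06 times the density of X (exact conditional 95% interval 8.41 to 9.78; two-sided permutation p = 0.0020, the smallest that 1000 random assignments can give). Taken one at a time, the autosomes lay between 6.07 and 14.5 times the density of X, so X stood below all 19 by more than they differed among themselves (2.39-fold). The gap held among strong peaks, with 53 peaks of score 1000 or more on X, a density 6.76 times lower than on the autosomes (5.16 to 9.04). The peaks that X did hold scored higher, with a median score of 118 against 87.3 on autosomes. Of the X peaks, 57.1% scored 100 or more (exact 95% interval 53.3% to 60.8%) against 42.8% of autosomal peaks (42.5% to 43.2%; Fisher's exact test, two-sided p = 1.04e-13). At 1000 or more the shares were 7.71% (5.83% to 9.97%) and 5.75% (5.61% to 5.91%; Fisher's exact test, two-sided p = 0.0324). Chromosome Y held 6 peaks, 5 of them with scores under 100 and 1 with a score of 1114.14.

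**Figure D2:**
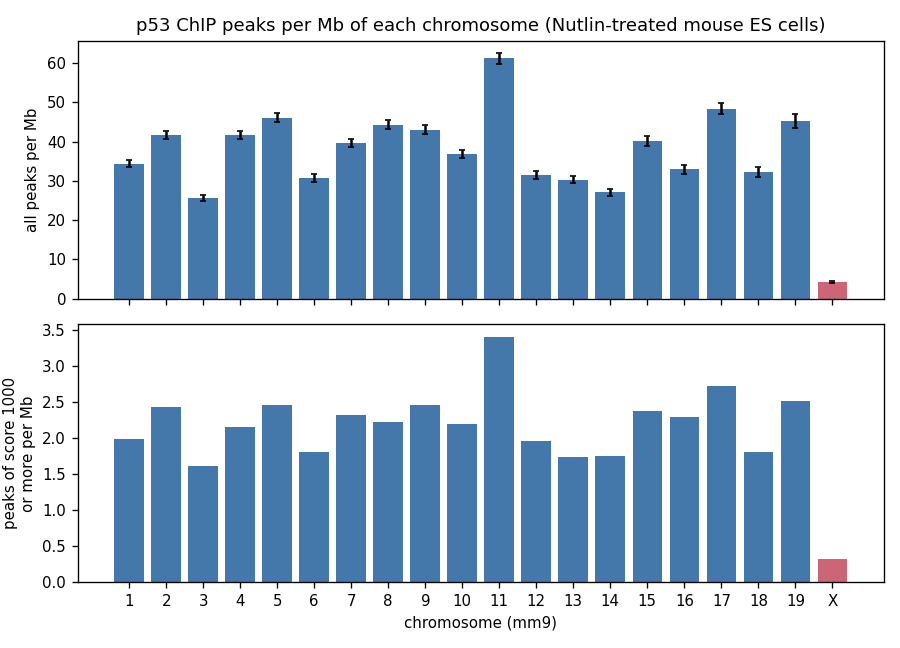
Peaks per Mb between the first and last peak of each mm9 chromosome, for all peaks (top; error bars are 95% Poisson intervals for counting error) and for peaks of score 1000 or more (bottom), with autosomes in blue and X in red. Chromosome X, at 4.22 and 0.325 per Mb, is below every autosome in both panels, and chromosome 11 is the highest in both.

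Along the autosomes, p53 peaks gathered in megabase-scale regions. The median 1 Mb bin held 26 peaks (quartiles 9 and 55, 2387 bins), 30 bins held none, and 206 bins (8.63%) held 100 or more and together 28.9% of the binned peaks. The highest bin had 255 peaks, whereas no bin exceeded 89 in 20 random placements of the autosomal peaks. This bin lay on chromosome 10 from 80000001 to 81000000, and its left neighbour, from 79000001, held 237. Of the 10 densest bins, 5 lay on the last part of chromosome 11, between 115000001 and 121000000, with 226 peaks in the bin that starts at 117000001 and 221 in the bin that starts at 119000001. The others in this group were on chromosome 8 from 124000001 (201 peaks), chromosome 5 from 114000001 (195 peaks) and chromosome 4 from 139000001 (181 peaks). On X the median bin held 3 peaks and the highest 24. The longest stretches without a peak were 7.51 Mb on chromosome 7, from 39018181 to 46529119, and 7.12 Mb on X, from 23403018 to 30525460. Assembly gaps were not used here, so an unassembled stretch and one without enrichment are not separated.

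**Figure D3:**
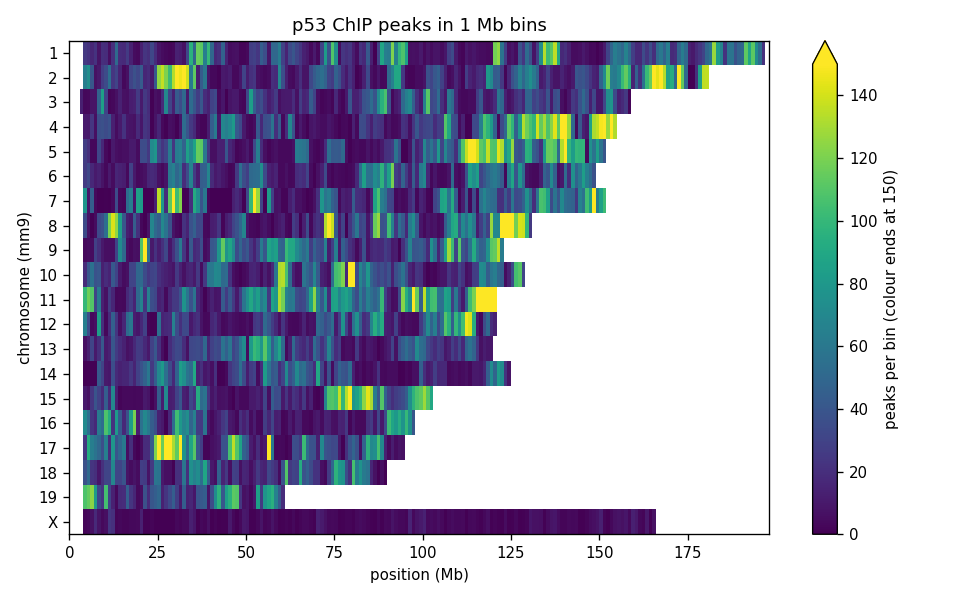
Number of p53 peaks in each 1 Mb bin (colour, ending at 150 peaks) along the autosomes and X, by mm9 position in Mb; white lies outside the first and last peaks. Dense bins form blocks, such as the distal end of chromosome 11 with up to 226 peaks per bin, while no bin of X holds more than 24.

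p53 peaks also lay close to one another. The median distance from a peak to the next was 8421 bases across the list, 8326 bases on autosomes and 91438 bases on X. The next peak started within 10 kb for 54.3% of peaks (50471 of 92903), against 34.0% on average in 1000 random placements on the same chromosomes (range 33.6% to 34.4%). The observed share was 1.60 times the random one (two-sided permutation p = 0.0020, the smallest possible). Among the 5000 highest-scoring peaks, 5.58% had a next peak within 10 kb. Random draws of 5000 peaks from the whole list gave 5.03% on average (range 4.16% to 6.17% over 1000 draws, two-sided permutation p = 0.0719). Spacing of the strongest peaks closer than that of the list as a whole was therefore not detectable. The draws carry the closeness of the whole list. Against random placements of these 5000 peaks, which gave 2.27% on average, the strongest peaks did lie closer together. When peaks were placed at random inside their own 1 Mb bin, the random share rose to 48.8% (48.4% to 49.2%) and the ratio fell to 1.11. The strongest peaks were not isolated from the rest of the list: 78.3% of peaks scoring 3100 or more (exact 95% interval 76.1% to 80.3%) had another peak within 10 kb on either side, against 74.0% of those under 100 (73.6% to 74.4%) and 70.3% of those from 1000 to under 3100 (68.8% to 71.7%).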

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

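Both tested results kept their direction and stayed past the 0.05 threshold in all 18 alternatives run. All 18 re-use peaks of the same list and gave the smallest p that the permutation test allows, so they are not independent support. Passing the threshold says little about size, since a spacing ratio of 1.04 also passed. The autosome-to-X density ratio of 9.06 ranged from 5.81 at scores of 200 or more (95% interval 5.10 to 6.64) to 9.06 without peaks wider than 4 kb. It was 6.81 at 100 or more, 6.09 at 500 or more, 8.10 at 3000 or more and 6.55 among the 5000 highest-scoring peaks. The spacing ratio of 1.60 ranged from 1.04 at 50 kb, where 85.1% of randomly placed peaks already have a next peak, to 2.46 among the 5000 highest-scoring peaks, where the random share is only 2.27% and the ratio has more room to rise; it was 1.90 at 5 kb, 1.11 for placements inside 1 Mb bins and 1.10 when peaks up to 1 kb apart were also merged. The size of the list depends on the score threshold by construction. A minimum of 100 left 39913 peaks, with a median width of 643 bases and a median score of 202. The 5000 highest-scoring peaks had a median width of 835 bases and a median score of 2058. Merging peaks up to 1 kb apart left 81024, with a median width of 531 bases and a median score of 92.0. With scores of exactly 3100 ranked first, by width, 0 of the 10 highest-scoring peaks remained, by construction, since all 10 score above 3100. Of 45 alternatives listed before the data were examined, 36 belong to results that need the mm9 sequence or annotation and were not run. No paired analysis was possible because each group has 1 library. Unknown read depth limits any statement on weak peaks, and leaving out a replicate was not possible with 1 library per group.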

Other observations

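The tests on the single X copy, on weak peaks on X, on chromosome ends, on neighbouring scores, on X peak widths and on the share of strong peaks in ranked bins were chosen after the results they bear on had been seen. Those on X bins, the score of 3100, spacing and bin variation were also added after the list had been examined, but before the values they test were computed.

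p53 peaks were more frequent toward the end of the autosomes far from the centromere. The last 10% of the length between the first and last peaks held 66.2 ± 30.6 peaks per Mb and the first 10% held 32.0 ± 20.9 (mean ± SD, n = 19 autosomes), a difference of 34.2 ± 31.9 per Mb (exact sign-flip permutation test, two-sided p = 3.28e-04). The last 10% was higher on 16 of 19 autosomes, with the widest gaps on chromosome 11 (131 against 49.4 per Mb) and chromosome 4 (101 against 19.5 per Mb). Chromosomes 17, 18 and 19 went the other way, with 32.8 against 49.5, 26.4 against 26.9 and 63.2 against 94.2 per Mb. On X the last and first 10% held 6.39 and 7.00 per Mb.

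Many of the widest peaks lay near the first peak of a few chromosomes. Of 18 peaks wider than 4 kb, 10 lay within 1 Mb of the first peak of their chromosome (55.6%), against 690 of the 92906 other peaks (0.743%). They are not independent: joined where up to 10 kb apart, the 18 peaks formed 14 regions, of which 6, on 5 chromosomes, lay within that 1 Mb. The widest, of 18655 bases, lay on chromosome 11 from 3028747 to 3047401 with a score of only 410.21, and chromosome 17 had 3 such peaks between 3006096 and 3034269. Further wide peaks lay inside chromosomes, such as 10580 bases on chromosome 10 from 74395071 to 74405650 and 6031 bases on chromosome 17 from 39979844 to 39985874, both with a score of 3100.

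Strong p53 peaks varied less between megabases than weak ones. In 2387 autosomal 1 Mb bins, the variance of the counts beyond counting error, divided by the squared mean, was 0.993 (95% bootstrap interval 0.931 to 1.06) for peaks scoring under 100, 0.890 (0.830 to 0.952) for 100 to under 1000, and 0.673 (0.606 to 0.744) for 1000 or more. The weak class exceeded the strong class by 0.320 (0.248 to 0.394), as a hypothesis written before the test had predicted, namely that weak peaks carry more of the variation between megabases. With bins ranked by their peaks of the middle class alone, strong peaks made up 14.5% (exact 95% interval 13.03% to 16.03%) of weak and strong peaks in the 25% of bins with the fewest, and 8.24% (7.95% to 8.54%) in the 25% with the most (Fisher's exact test, two-sided p = 1.05e-20). The Fisher test and these intervals count peaks, which gather in bins and are not independent, so they may overstate the evidence. Scores of neighbouring peaks were nearly unrelated (Spearman rho of 0.016 over 92903 neighbouring pairs, and 0.017 over 34768 pairs up to 5 kb apart), and the share of the 5000 highest-scoring peaks near a next one (5.58%) lay within the range of random draws of 5000 peaks (4.16% to 6.17%).

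As the cause of the low number of peaks on chromosome X, loss of weak peaks alone is argued against by the ratio of 6.76 (5.16 to 9.04) at scores of 1000 or more, where each of the 19 autosomes was at least 4.97 times above X. Empty stretches were more frequent on X, with 22 of 162 bins empty (13.6%) against 30 of 2387 on autosomes (1.26%), but as the whole cause they are argued against by occupied 1 Mb bins, which held 6.75 times more peaks on autosomes at the median (95% bootstrap interval 6.50 to 9.67). A single copy of X that divides scores by 2 is argued against by the density of autosomal peaks of 100 or more, still 3.88 times (3.60 to 4.19) that of all X peaks. A single copy read against an unchanged genome-wide background may lower scores by more than a factor of 2: autosomal scores would have to be divided by 9.15 to give the X density of all peaks, by 7.78 at a score of 200 and by 6.01 at 500, and this cannot be told apart from fewer bound sites because the list gives no fold over input. X peaks were also narrower than autosomal peaks of matched score (451 bases against 548 on average, below all 10000 random lists). The labels do not give the sex of the line. The list holds 6 peaks on Y, 1 of them with a score of 1114.14, but whether the cells carry a Y chromosome was not tested. No biological explanation was tested.

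The pile-up of 1390 peaks at exactly 3100 is consistent with a fixed value that stands for p-values too small to be stored. If so, these peaks should be at least as wide as those scored above 3100, and they were wider by 160 bases at the median (95% bootstrap interval 77.0 to 213). A ranking of this list by score may therefore put its strongest peaks behind 116 weaker ones. Width is only a stand-in for strength here, and wide repeat-rich regions could also raise it.

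Splitting of peaks over gaps of up to 1 kb and variation between 1 Mb bins did not account for all of the closeness of peaks, alone or together. Splitting of wide enrichment by the caller over gaps of up to 1 kb, as the whole cause, is argued against by the ratio of 1.56 to random placements after such peaks were merged. Splitting over wider gaps, up to the 10 kb that defines closeness, was not tested. Variation between megabases, tested by placing peaks at random inside 1 Mb bins, took the ratio from 1.60 to 1.11, with 54.3% observed against at most 49.2% in 1000 placements. With both applied, 47.6% of merged peaks had a next peak within 10 kb against 43.0% to 43.8% in the placements, a ratio of 1.10. Most of the excess may thus belong to the megabase scale, with a remainder at shorter range. Placement inside 1 Mb bins cannot separate this remainder from peak density that varies below 1 Mb. Unequal mappability inside a bin was not tested and stays open, since the genome sequence was not used here.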
